A study of Mus musculus with 40 samples.

How the data were processed

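RNA was measured in mouse embryonic stem cells of 2 genotypes, wild type and homozygous GLP 3A, each untreated and after 1 uM all-trans retinoic acid (RA). Each of the 4 groups had 2 libraries, 8 in all. Per the labels' protocols, the cells were moved from feeders in serum and LIF to feeder-free 2i medium, and LIF was withdrawn when RA was added. RNA was extracted with Trizol and treated with DNase, per the labels' protocols; the strand protocol and the length of RA treatment are not given in the sources used here. The series has 40 samples, and the 32 others, of chromatin and input DNA, are not analysed here.

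The files hold RPKM per gene symbol and locus, per the file headers. The submitters' processing notes name Bowtie 0.12.7, SAMtools, TopHat and Cufflinks with genome build mm9; they state no version for the other tools. How reads in genes that overlap were assigned is not given in the sources used here. Each file lists 23234 symbols, 23240 in any and 23228 in all, and the 12 not in all files were left out. No symbol is repeated within a file. Symbols at the same locus number 4164, in 1793 loci, and their values are uncertain where reads could be split between them. Among the genes named in the report these include H19 (with Mir675), Tsix (Xist), Igf2, Peg3, Msx1 and their antisense genes, Sox2 (Sox2ot), Nanog (Nanogpd), Hoxa5 (Hoxa3, Hoxa4 and Hoxa6), Tagln, Mest (Copg2), Nrp2, Fbxo15, Csn3, Sfmbt2, Raet1c,Raet1e, Atp6v0c-ps2 (Atp6v0c) and Pisd-ps3 (Pisd-ps1). Gstp2, the Rhox genes, the histone genes and ribosomal protein genes have near-identical copies and are uncertain in the same way.

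Library depth was estimated from the files, which hold no read counts. Low RPKM values of a gene differ by whole reads, so the ratios of the smallest steps between values at or under 0.15 RPKM were matched to ratios of whole numbers up to 4 with a tolerance of 1.5%. The relative depth was 0.96 to 1.24 for replicate 1 and 0.44 to 0.57 for replicate 2. A value near 0 therefore rests on fewer reads in replicate 2. At these depths 16.0% to 25.6% of the ratios matched, against 6.9% to 8.3% at random depths, so the depths are rough estimates. Zeros were used as deposited. A 0 in a gene whose other library of the group was at 5 RPKM or more occurred 43 times outside short RNA genes and 281 times among the 728 short RNA genes (Mir, Snord, Snora and Scarna), 188 of which were tested.

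Differences were tested with limma 3.58.1 in R 4.3.3 on log2(RPKM + 1). The model had the 4 group means over all 8 libraries, so the groups share 1 estimate of spread per gene, and an empirical Bayes prior with an intensity trend. Moderated tests were two-sided and adjusted by Benjamini-Hochberg over the 13198 genes with at least 1 RPKM in at least 2 libraries. A gene was called at an adjusted p under 0.05, and standard errors are the moderated ones. There were 5 comparisons: GLP 3A against wild type untreated and with RA, RA against untreated in each genotype, and the difference of these RA responses. The difference between genotypes in their response was tested as an interaction.

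The 24 gene lists were written down before the data were examined, as were the tests, the samples in each fit, the rule for naming genes and most of the other settings tried. Lists with at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison. The same test with a correlation estimated from the data was run beside it, and no list was called with it. The lists of Magea and 2-cell-like genes had 0 genes tested, and the mitochondrial list had 0 genes in the files. For each list, genes were also counted after adjustment over that list alone. Calls per chromosome were compared by two-sided Fisher's exact tests, adjusted over 40 tests. Pearson's r across genes describes likeness only.

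Genes were named by this rule: the 10 largest called increases and decreases of each comparison whose groups do not overlap, without Gm, Rik and identifier names, together with a fixed set of genes that includes Ehmt1, Ehmt2, Pou5f1, Nanog, Sox2, Zfp42, Cyp26a1, Rarb, Gata6 and Sox17. From each list up to 4 called and 2 uncalled members with the largest change were eligible. Some genes that meet the rule are not reported here. Applying the rule a second time without short RNA genes and naming Alb were choices made after the values were seen. The chromosome tests were not among the choices made beforehand, and the test of whole autosomes was written before its result was seen.

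The other settings fixed beforehand were pseudocounts of 0.1 and 0.5, no filter and a filter of 5 RPKM, median-of-ratios and quantile scaling, no intensity trend, robust empirical Bayes, only the 4 libraries compared, the replicate number as a block, a 2-fold threshold, another treatment of repeated symbols, and each library left out in turn. Added after the values were seen were suspect zeros as missing, tests without the genes 4-fold higher in replicate 2, without short RNA genes or without chromosomes 1 and 11, and each replicate number alone. Lists of liver, fetal liver and blood, intestine, kidney, skeletal muscle, pancreas, brain and immune genes were also added then.

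The limma test was tested on simulated data shaped like the untreated comparison, with 200 changed genes among 11678 to 11709 in 5 runs. It recovered 91% of 2-fold and 98.4% of 4-fold changes, with 4.1% false calls and 0 of the wrong sign. A list of 20 genes shifted by 0.7 was called in 5 of 5 runs, and 0 unshifted lists were called. Changed and shifted genes were drawn only from those above 5 RPKM in untreated wild type. Each gene was drawn independently of the others, with the same spread in all 8 libraries. The simulation therefore cannot show how correlated genes or unequal spreads between groups affect the calls. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for reading, chromosome tests and plots.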

Results

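Mouse embryonic stem cells with a normal Ehmt1 gene and cells homozygous for the GLP 3A mutation were compared by RNA-seq, each genotype untreated and after retinoic acid (RA). Ehmt1 encodes GLP, a methyltransferase of histone H3 lysine 9, and the series asks what part GLP plays in passing on histone marks. RA makes stem cells differentiate. It was given at 1 uM while the self-renewal factor LIF was removed, and the labels give no length of treatment. Effects of RA and of LIF removal cannot be told apart here, so differences with RA below are those of both. The 4 groups held 2 libraries each, 8 in all, each deposited as RPKM (reads scaled by gene length and by library depth) for 23234 gene symbols. Read counts are not in the files, so depth was estimated from the spacing of the lowest values. Relative to replicate 1 of untreated wild type, the replicate 1 libraries lay between 0.96 and 1.24 and the replicate 2 libraries between 0.44 and 0.57. RPKM summed to 748556 and 762180 in untreated wild type, 822877 and 772615 in untreated GLP 3A, 529706 and 554854 in RA-treated wild type and 509341 and 513354 in RA-treated GLP 3A. Genes at 1 RPKM or more numbered from 11344 in untreated wild type replicate 1 to 12369 in RA-treated GLP 3A replicate 2. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these samples.

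Ehmt1 itself was measured first. The gene (chromosome 2, 24646293 to 24775110 in mm9) stood at 18.4 and 17.6 RPKM in untreated wild type, 14.1 and 14.3 in untreated GLP 3A, 24.4 and 23.5 in RA-treated wild type and 13.0 and 13.9 in RA-treated GLP 3A. It was lower in GLP 3A in both states, with a log2 difference of -0.32 ± 0.07 (SE, n = 2 per group, adjusted p = 0.0334) without RA and -0.79 ± 0.07 (adjusted p = 0.0041) with RA. The call without RA ended when untreated wild-type replicate 1 (adjusted p = 0.195) or 2 (0.145) or untreated GLP 3A replicate 1 (0.195) or 2 (0.165) was left out, and the call with RA was kept in all 8 such fits. Ehmt1 was higher with RA in wild type (0.40 ± 0.07, adjusted p = 0.00229). In GLP 3A the RA difference was -0.08 ± 0.07 as deposited (adjusted p = 0.35) and 0.003 under median-of-ratios scaling. The difference of these RA responses was -0.47 ± 0.10 (adjusted p = 0.0698). Ehmt2, which encodes the partner enzyme G9a, differed by -0.08 ± 0.13 without RA and -0.30 ± 0.13 with RA between the genotypes, and neither was called. The files hold no sequence, so these levels show that the labelled groups differ but not that the mutation is present.

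How undifferentiated GLP 3A cells differed from wild type was the first comparison, GLP 3A minus wild type without RA. The largest rise outside short RNA genes was that of Cyct, the testis form of cytochrome c, from 3.95 and 3.45 RPKM in wild type to 58.4 and 55.3 in GLP 3A (log2 difference 3.62 ± 0.20, SE, n = 2 per genotype, adjusted p = 6.0e-04). The X-linked genes Fmr1nb (3.34 ± 0.19), Pnma5 (3.02 ± 0.14) and Klhl13 (2.75 ± 0.21) rose, as did the homeobox genes Rhox9 (2.60 ± 0.38) and Rhox6 (2.49 ± 0.49). Gstp2, a glutathione transferase (3.07 ± 0.34), the metallothionein gene Mt4 (2.80 ± 0.28), the ubiquitin-like gene Ubd (2.57 ± 0.11) and Smtnl1 (2.56 ± 0.18) completed the 10 largest. Large decreases were those of Fxyd6, a regulator of the sodium pump (-2.71 ± 0.14), Adam23 (-2.46 ± 0.10), Ube2l6, an enzyme of ISG15 conjugation (-2.09 ± 0.19), the stathmin gene Stmn3 (-2.07 ± 0.15) and the interleukin receptor gene Il3ra (-2.06 ± 0.20). Adam23 lies on chromosome 1. The pseudogenes Pisd-ps3 (-2.78 ± 0.64) and Atp6v0c-ps2 (-2.06 ± 0.20) also fell. Atp6v0c-ps2 shares its locus with the gene it resembles, Atp6v0c, and Pisd-ps3 with another pseudogene, Pisd-ps1. Among the 10 largest increases and decreases with short RNA genes counted, Mir709, Mir675 and Mir215 were listed at 0 in both wild-type libraries, and Mir692-1, Snord82, Mir697, Mir3572 and Mir1186 in both GLP 3A libraries.

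Most genes of the pluripotent state were not called in this comparison. Of 32 pluripotency genes tested, 1 rose, 1 fell and 30 were not called, with the same counts adjusted over the list alone. Dppa3, a maternal factor, rose by 2.03 ± 0.24 (adjusted p = 0.0058), and Zfp42, the Rex1 gene, fell from 313.7 and 290.1 RPKM to 66.4 and 63.2 (-2.20 ± 0.29, adjusted p = 0.00893). Pou5f1 (-0.26 ± 0.74), Nanog (0.37 ± 0.31), Sox2 (-0.12 ± 0.23) and Fbxo15 (1.09 ± 0.60) were not called. Their standard errors come from the spread in all 8 libraries, the RA-treated ones included. Fbxo15 stood at 50.4 and 45.9 RPKM in untreated wild type and at 103.6 and 103.4 in untreated GLP 3A. With RA it stood at 5.0 and 1.0 in wild type and at 14.9 and 5.11 in GLP 3A. A gene without a call was therefore not shown to be alike in the untreated genotypes. Of 15 genes of formative and primed pluripotency, 3 rose and 2 fell (6 and 3 adjusted over the list alone). Zic2 (1.72 ± 0.27), the DNA methyltransferase gene Dnmt3b (1.20 ± 0.15) and Zic5 (0.96 ± 0.16) were higher and Tcf15 (-1.24 ± 0.12) lower. Among 13 trophoblast genes, 4 rose and 0 fell (7 and 0 adjusted over the list alone). With Rhox6 and Rhox9 these were the keratins Krt19 (1.09 ± 0.20) and Krt18 (0.87 ± 0.21), while Krt8 stood at 0.85 ± 0.24 without a call. Krt19 lies on chromosome 11. Imprinted genes went both ways, 5 rising and 3 falling among 34 (7 and 6 adjusted over the list alone): H19 (1.41 ± 0.16), Sfmbt2 (1.29 ± 0.22) and Peg3 (1.01 ± 0.19) rose and Grb10 (-1.28 ± 0.18) fell. Of 20 p53 target genes, 0 rose and 2 fell (0 and 2 adjusted over the list alone), Aen (-0.93 ± 0.07) and Phlda3 (-0.84 ± 0.12), with Btg2 at -0.37 ± 0.10 not called. This was the only list called, with a median of -0.19 (-0.17 in replicate 1 alone and -0.24 in replicate 2 alone, adjusted p = 0.0129, and adjusted p = 0.961 with an estimated correlation). Phlda3 and Btg2 lie on chromosome 1, and without chromosomes 1 and 11 the median was -0.18 with adjusted p = 0.0673. Of 32 Hox genes 0 were called by limma (2 lower at an unadjusted p under 0.05), and of 23 genes of the RA pathway 0 rose and 2 fell (the same adjusted over the list alone), among them Gbx2, which is also on chromosome 1. Cyp26a1, Rarb, Gata6 and Sox17 were at 0.612 RPKM or less in all untreated libraries and none was called.

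In total 1541 of 13198 genes tested differed without RA, 993 higher and 548 lower in GLP 3A, and 277 of them by 2-fold or more (192 higher and 85 lower). All 1541 had the same sign in both replicate numbers, which a call with 2 libraries per group all but requires. Of all genes tested, 410 were 2-fold apart in replicate 1 alone and 437 in replicate 2 alone. The share of higher calls was 64.4% as deposited, 50.1% with median-of-ratios scaling and 54% with quantile normalization. With only the 4 untreated libraries in the fit the count was 3450. It rested on every untreated library: it was 234 without wild-type replicate 1, 206 without wild-type replicate 2, 260 without GLP 3A replicate 1 and 237 without GLP 3A replicate 2, where 19, 22, 20 and 20 of the 38 named genes with a call kept it. The 19 that kept theirs whichever library was left out included Cyct, Fmr1nb, Pnma5, Klhl13, Mt4, Ubd, Smtnl1, Fxyd6, Adam23, Ube2l6, Stmn3, Il3ra, Tcf15 and Aen. The other 19 lost theirs in at least 1 of these fits: Ehmt1, Zfp42, Dppa3, Zic2, Zic5, Dnmt3b, Rhox6, Rhox9, Krt18, Krt19, Gstp2, H19, Sfmbt2, Peg3, Grb10, Phlda3, Gbx2, Uty and Pisd-ps3. With each of the 4 untreated libraries left out, adjusted p was 0.0666 to 0.0748 for Zfp42, 0.0516 to 0.0614 for Dppa3, 0.0831 to 0.101 for Zic2 and 0.056 to 0.0732 for Dnmt3b.

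Part of the genotype difference lay on 2 chromosomes in both states. Genes on chromosome 1 were lower in GLP 3A, with a median of -0.24 without RA (-0.24 in replicate 1 alone, -0.22 in replicate 2 alone) and -0.31 with RA (-0.30 and -0.31). Genes on chromosome 11 were higher, with medians of 0.24 without RA (0.24 and 0.24) and 0.24 with RA (0.27 and 0.20). The 17 other autosomes had medians from 0.00 to 0.08 without RA and from -0.06 to 0.00 with RA, and the X chromosome 0.05 and -0.03. Of 710 tested genes on chromosome 1, 148 were called lower without RA (20.8% against 3.2% of all other genes; two-sided Fisher's exact test, adjusted p = 4.4e-64 over 40 tests) and 212 with RA (29.9% against 3.9%, adjusted p = 4.6e-106). Of 1114 on chromosome 11, 220 were called higher without RA (19.7% against 6.4%, Fisher's exact test, adjusted p = 6.2e-43) and 201 with RA (18.0% against 4.1%, adjusted p = 4.0e-58). Neighbouring genes are not independent, so these p-values describe the lists of calls. Refitted without both chromosomes, 991 genes were called without RA (662 higher, 329 lower) and 724 with RA (379 higher, 345 lower). The 4 Y-linked genes tested were higher in GLP 3A in both states: Ddx3y by 2.39 ± 0.11 without RA and 2.39 ± 0.11 with RA, Eif2s3y by 2.09 ± 0.12 and 1.43 ± 0.12, Kdm5d by 1.96 ± 0.14 and 1.92 ± 0.14, and Uty by 0.73 ± 0.14 and 0.75 ± 0.14. Kdm5d stood at 0.06 to 0.12 RPKM in the 4 wild-type libraries and at 2.63 to 3.74 in the 4 GLP 3A libraries. Tsix, the antisense RNA of Xist, was lower without RA (-1.32 ± 0.09, adjusted p = 0.00153) and at -0.19 ± 0.09 with RA; the files do not separate strands at this locus.

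**Figure D1:**
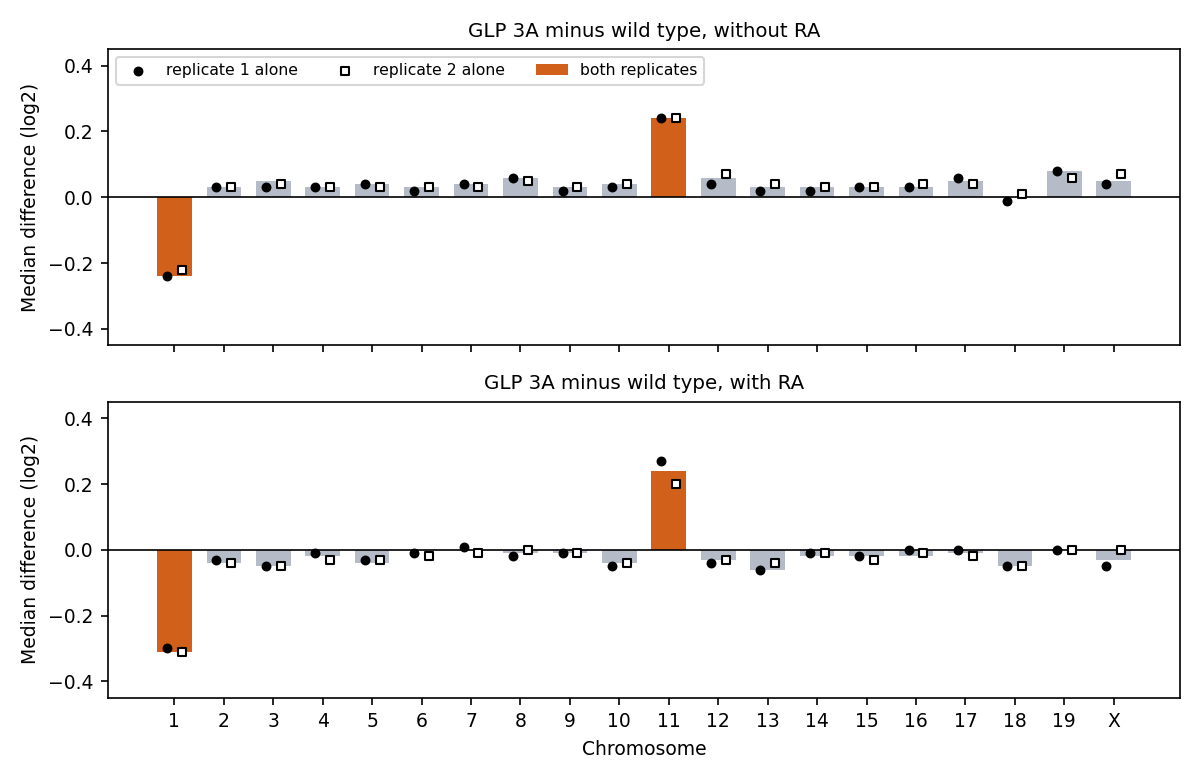
Median log2 difference of GLP 3A minus wild type over the tested genes of each chromosome, without RA (top) and with RA (bottom). Bars are from both replicates and points from replicate 1 or replicate 2 alone; chromosome 1 lies at -0.24 and -0.31 and chromosome 11 at 0.24 in both states.

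How wild-type cells answered RA was the reference for the mutant. Cyp26a1, the enzyme that breaks RA down, rose from 0.08 and 0.13 RPKM to 218.0 and 125.4 (log2 difference 7.23 ± 0.30, n = 2 per group, adjusted p = 1.0e-05), and Pou5f1, the gene of Oct4, fell from 1183 and 1250 RPKM to 14.6 and 2.20 (-7.43 ± 0.74, adjusted p = 2.3e-04). The largest other increases were in the hedgehog pathway gene Gas1 (7.11 ± 0.33), the imprinted genes H19 (7.07 ± 0.16) and Igf2 (6.42 ± 0.09), the smooth muscle genes Acta2 (6.87 ± 0.35) and Tagln (6.73 ± 0.21), the myelin gene Pmp22 (6.65 ± 0.24), the RA-binding protein gene Crabp2 (6.63 ± 0.37), Hoxa5 (6.64 ± 0.26) and Hoxb2 (6.11 ± 0.27). The largest other decreases were in the Nodal co-receptor gene Tdgf1 (-8.24 ± 0.32), the hormone precursor gene Trh (-8.17 ± 0.37), the threonine dehydrogenase gene Tdh (-6.95 ± 0.54), Esrrb (-6.82 ± 0.37), Klf2 (-6.12 ± 0.28), Nanog (-6.11 ± 0.31), Fgf4 (-6.09 ± 0.19), Upp1 (-5.90 ± 0.65) and Mylpf (-5.83 ± 0.43). Sox2 (-3.25 ± 0.23) and Zfp42 (-5.12 ± 0.29) fell as well. Of the 10 largest decreases with short RNA genes counted, 7 were Snord37, Snord73a, Mir1949, Snord82, Snord91a, Mir142 and Scarna10, all listed at 0 in both RA-treated wild-type libraries.

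Whole groups of genes moved with RA in wild type. Of 32 pluripotency genes, 31 fell and 1 was not called, Lin28a at -0.50 ± 0.20 (32 fell adjusted over the list alone). The pluripotency median was -4.28 (adjusted p = 1.3e-11, and adjusted p = 0.315 with an estimated correlation). Of 32 Hox genes, which pattern the body axis, 31 rose and 0 fell (31 adjusted over the list alone), with Hoxa5 and Hoxb2 among them. The Hox median was 3.91 (adjusted p = 3.1e-11, and adjusted p = 0.204 with an estimated correlation). Of 23 genes of the RA pathway, 18 rose and 3 fell (18 and 3 adjusted over the list alone), among them Cyp26b1 (5.93 ± 0.14), Meis1 (5.81 ± 0.20) and the receptor gene Rarb (4.38 ± 0.13). The RA pathway median was 3.93 (adjusted p = 3.9e-06, and adjusted p = 0.111 with an estimated correlation). Genes of fibroblasts rose in 20 and fell in 1 of 21 (the same adjusted over the list alone), with the collagens Col1a2 (5.37 ± 0.34) and Col3a1 (4.42 ± 0.14). The fibroblast median was 2.78 (adjusted p = 1.7e-07, and adjusted p = 0.145 with an estimated correlation). Imprinted genes rose in 25 and fell in 3 of 34 (27 and 3 adjusted over the list alone), with Dlk1 (5.26 ± 0.31) and Mest (4.41 ± 0.14) beside H19 and Igf2. The imprinted gene median was 1.77 (adjusted p = 5.9e-07, and adjusted p = 0.191 with an estimated correlation). Endoderm genes rose in 14 and fell in 1 of 22 (the same adjusted over the list alone): Plat (4.86 ± 0.13), Col4a2 (4.81 ± 0.68), Col4a1 (4.64 ± 0.77), Sox17 (4.38 ± 0.27) and Gata6 (3.66 ± 0.27). The endoderm median was 2.40 (adjusted p = 0.00106, and adjusted p = 0.459 with an estimated correlation). It was 3.42 in replicate 1 alone and 1.40 in replicate 2 alone, and 1.58 with RA-treated wild-type replicate 1 left out. Trophoblast genes rose in 10 and fell in 2 of 13 (the same adjusted over the list alone), led by Krt18 (5.13 ± 0.21) and Krt8 (4.82 ± 0.24). The trophoblast median was 2.39 (adjusted p = 0.00376, and adjusted p = 0.413 with an estimated correlation). Of 20 p53 target genes, 13 rose and 3 fell (the same adjusted over the list alone), Perp by 1.98 ± 0.20. The p53 target median was 0.53 (adjusted p = 0.00518, and adjusted p = 0.204 with an estimated correlation).

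Of 20 S phase genes, 16 fell and 0 rose (the same adjusted over the list alone), with Ung (-1.92 ± 0.09), Mcm5 (-1.24 ± 0.12) and Mcm3 (-1.23 ± 0.11). The S phase median was -0.95 (adjusted p = 2.1e-05, and adjusted p = 0.145 with an estimated correlation). Of 20 genes of G2 and M phase, 13 fell and 0 rose (the same adjusted over the list alone), Ccnb1 by -0.88 ± 0.06. The G2 and M phase median was -0.34 (adjusted p = 0.00372, and adjusted p = 0.413 with an estimated correlation). Ribosomal protein genes fell in 70 of 77 (71 adjusted over the list alone) with a median of -0.60 as deposited, which turned to 0.06 with quantile normalization (adjusted p = 2.8e-10 as deposited, and adjusted p = 0.191 with an estimated correlation). Genes of the H3K9 methylation machinery rose in 3 and fell in 16 of 26 (the same adjusted over the list alone), while Ehmt2 was at -0.29 ± 0.13 without a call. The machinery median was -0.36 (adjusted p = 0.00993, and adjusted p = 0.459 with an estimated correlation). Germline genes rose in 2 and fell in 11 of 19 (the same adjusted over the list alone; median -0.77, adjusted p = 0.0217, and adjusted p = 0.675 with an estimated correlation), and mesoderm genes rose in 7 and fell in 2 of 10 (the same adjusted over the list alone; median 1.63, adjusted p = 0.0434, and adjusted p = 0.287 with an estimated correlation). The germline call ended without RA-treated wild-type replicate 2 (adjusted p = 0.096), and the mesoderm call without RA-treated GLP 3A replicate 1 (adjusted p = 0.0541) or 2 (adjusted p = 0.0544) and also without the genes of chromosomes 1 and 11 (median 1.34, adjusted p = 0.377). In total 9041 genes changed, 4453 rising and 4588 falling, 3388 of them by 2-fold or more; 3439 genes were 2-fold apart in replicate 1 alone and 3590 in replicate 2 alone.

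GLP 3A cells also answered RA. Pmp22 rose by 7.25 ± 0.24 (n = 2 per group, adjusted p = 6.5e-06), Acta2 by 7.04 ± 0.35, Cyp26a1 by 6.76 ± 0.30, Hoxa5 by 6.61 ± 0.26, H19 by 6.57 ± 0.16, Tagln by 6.09 ± 0.21, Hoxb2 by 6.06 ± 0.27, the meiotic gatekeeper Stra8 by 6.04 ± 0.24, Igf2 by 6.03 ± 0.09 and Gas1 by 5.97 ± 0.33. Trh fell from 878.7 and 811.0 RPKM to 4.11 and 1.26 (-7.96 ± 0.37, adjusted p = 1.5e-05). The other large decreases were in Tdgf1 (-6.88 ± 0.32), Tdh (-6.52 ± 0.54), Sept1 (-6.00 ± 0.29), Pou5f1 (-5.79 ± 0.74), Fgf4 (-5.75 ± 0.19), Atp6v0c-ps2 (-5.74 ± 0.20), the oligodendrocyte factor gene Olig2 (-5.21 ± 0.10), Esrrb (-5.16 ± 0.37) and Nr0b1 (-5.11 ± 0.16). With short RNA genes counted, Snord110, Snord34, Snord57, Snord69, Snord73a, Snord52, Snora75 and Snora61 fell the most, each listed at 0 in at least 1 RA-treated GLP 3A library. Nanog (-4.23 ± 0.31), Sox2 (-3.73 ± 0.23) and Zfp42 (-2.62 ± 0.29) fell, Rarb (4.11 ± 0.13), Gata6 (3.41 ± 0.27) and Sox17 (3.04 ± 0.27) rose, and Ehmt2 fell by 0.51 ± 0.13 (adjusted p = 0.0109). The Ehmt2 call ended without untreated GLP 3A replicate 1 (adjusted p = 0.0685), and the other named genes kept theirs in all 8 such fits.

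By group, 32 of 32 pluripotency genes fell in GLP 3A with RA (32 adjusted over the list alone). The pluripotency median was -3.46 (adjusted p = 3.9e-10, and adjusted p = 0.347 with an estimated correlation). Hox genes rose in 30 of 32 (30 adjusted over the list alone; median 3.07, adjusted p = 3.9e-10, and adjusted p = 0.219 with an estimated correlation), and genes of the RA pathway rose in 17 and fell in 2 of 23 (the same adjusted over the list alone; median 4.07, adjusted p = 1.9e-06, and adjusted p = 0.1 with an estimated correlation). Cyp26b1 (5.88 ± 0.14) and Meis1 (5.86 ± 0.20) were among the latter, and Crabp1 (-0.50 ± 0.39) was not called. Fibroblast genes rose in 20 and fell in 1 of 21 (median 2.60, adjusted p = 7.8e-08, and adjusted p = 0.134 with an estimated correlation), imprinted genes rose in 24 and fell in 2 of 34 (median 1.25, adjusted p = 1.9e-06, and adjusted p = 0.159 with an estimated correlation), and trophoblast genes rose in 11 and fell in 2 of 13 (median 2.29, adjusted p = 0.0011, and adjusted p = 0.347 with an estimated correlation), Krt18 by 4.86 ± 0.21 and Krt19 by 4.67 ± 0.20. Adjusted over the list alone, the fibroblast and trophoblast counts did not change and the imprinted ones were 25 and 2. Endoderm genes rose in 11 and fell in 1 of 22 (the same adjusted over the list alone), with Plat (4.36 ± 0.13), Col4a2 (4.09 ± 0.68) and Col4a1 (3.87 ± 0.77). The endoderm median was 1.66, with 2.34 in replicate 1 alone and 1.09 in replicate 2 alone (adjusted p = 0.00193, and adjusted p = 0.47 with an estimated correlation). Of 20 p53 target genes, 13 rose and 2 fell (the same adjusted over the list alone), Perp by 2.85 ± 0.20 and the death receptor gene Fas by 2.11 ± 0.14. The p53 target median was 1.06 (adjusted p = 4.8e-04, and adjusted p = 0.159 with an estimated correlation). S phase genes fell in 18 of 20 (18 adjusted over the list alone; median -1.03, adjusted p = 8.2e-06, and adjusted p = 0.134 with an estimated correlation) and G2 and M phase genes in 18 of 20 (18 adjusted over the list alone; median -0.57, adjusted p = 1.9e-04, and adjusted p = 0.337 with an estimated correlation). The H3K9 methylation machinery rose in 2 and fell in 19 of 26 (the same adjusted over the list alone), with the chromatin remodeller gene Hells at -1.65 ± 0.09. The machinery median was -0.50 (adjusted p = 0.0011, and adjusted p = 0.347 with an estimated correlation). Ribosomal protein genes fell in 73 of 77 (73 adjusted over the list alone) with a median of -0.70 as deposited, which turned to 0.14 with quantile normalization (adjusted p = 3.9e-10 as deposited, and adjusted p = 0.159 with an estimated correlation). In total 9289 genes changed, 4262 rising and 5027 falling, 3570 of them by 2-fold or more; 3691 genes were 2-fold apart in replicate 1 alone and 3751 in replicate 2 alone.

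**Figure D2:**
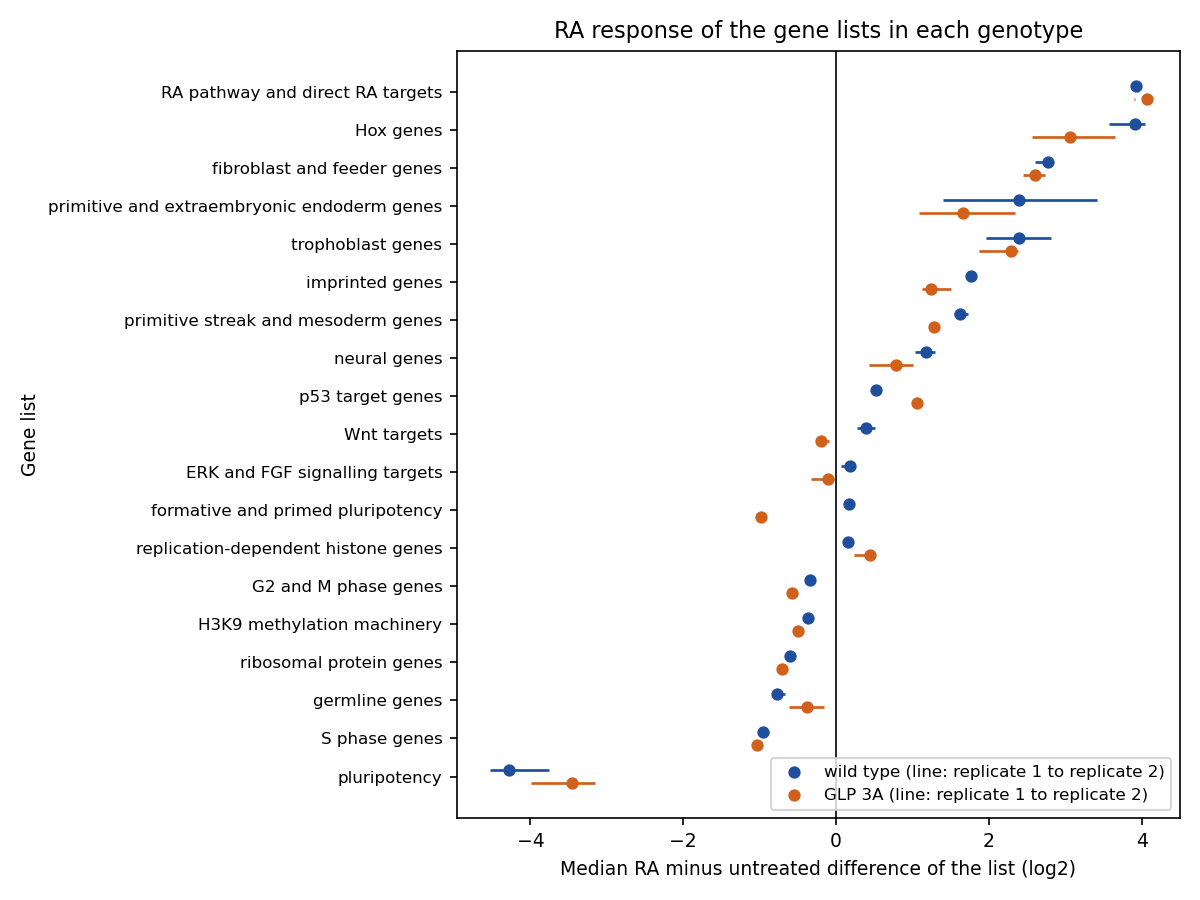
Median log2 difference of RA minus untreated over each gene list with at least 5 genes tested, in wild type and in GLP 3A. Points are from both replicates and lines join the medians of replicate 1 alone and replicate 2 alone; the pluripotency genes lie at -4.28 in wild type and -3.46 in GLP 3A.

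With RA, GLP 3A and wild-type cells were then compared directly. Nanog was at 13.1 and 6.30 RPKM in GLP 3A against 1.51 and 0.81 in wild type (log2 difference 2.25 ± 0.31, SE, n = 2 per genotype, adjusted p = 0.0146). Higher too were Dppa3 (1.99 ± 0.24), Klf2 (1.81 ± 0.28) and Tdgf1 (1.80 ± 0.32). In all, 7 of 32 pluripotency genes were higher in GLP 3A and 0 lower (10 and 0 adjusted over the list alone), with a median of 0.44 (0.66 in replicate 1 alone and 0.33 in replicate 2 alone; adjusted p = 4.4e-04, and adjusted p = 0.564 with an estimated correlation). Pou5f1 (1.38 ± 0.74), Fbxo15 (1.50 ± 0.60), Zfp42 (0.30 ± 0.29) and Sox2 (-0.61 ± 0.23) were not called. Hox genes were lower in 8 and higher in 1 of 32 (10 and 1 adjusted over the list alone): Hoxc9 (-1.60 ± 0.23), Hoxc10 (-1.44 ± 0.21), Hoxa9 (-1.38 ± 0.11) and Hoxc8 (-1.30 ± 0.31) were lower and Hoxb1 (0.86 ± 0.09) higher. The Hox median was -0.49, with -0.59 in replicate 1 alone and -0.42 in replicate 2 alone (adjusted p = 8.0e-04, and adjusted p = 0.557 with an estimated correlation). Among 13 trophoblast genes 3 were higher and 1 lower (5 and 1 adjusted over the list alone): Rhox9 (1.90 ± 0.38), Krt7 (1.27 ± 0.17), Krt19 (0.96 ± 0.20) and Gata3 (-0.67 ± 0.12). Krt19 and Hoxb1, the Hox gene called higher, lie on chromosome 11. The trophoblast median was 0.64, with 0.91 in replicate 1 alone and 0.67 in replicate 2 alone (adjusted p = 0.00198, and adjusted p = 0.557 with an estimated correlation). Leaving out RA-treated wild-type replicate 2 ended the calls of the pluripotency list (median 0.23, adjusted p = 0.0755) and of the trophoblast list (median 0.56, adjusted p = 0.0694). The pluripotency median was 0.71 without RA-treated wild-type replicate 1, 0.14 without RA-treated GLP 3A replicate 1 and 0.86 without RA-treated GLP 3A replicate 2. The Hox median was -0.26 without RA-treated wild-type replicate 2, -0.18 without RA-treated GLP 3A replicate 1 (adjusted p = 0.0466) and -0.84 without RA-treated GLP 3A replicate 2, where the trophoblast median was 1.09.

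**Figure D3:**
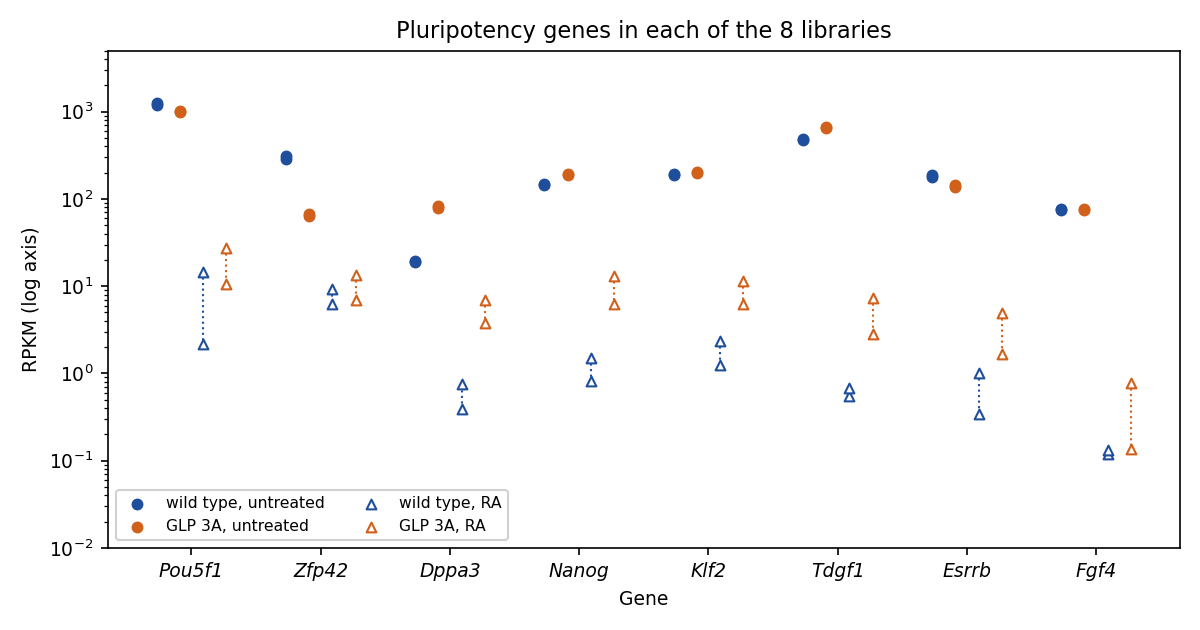
RPKM of 8 pluripotency genes in each library on a log axis, with a line joining the 2 libraries of a group. With RA, Nanog lies at 13.1 and 6.30 RPKM in GLP 3A and at 1.51 and 0.81 in wild type.

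Single genes with large differences after RA included several seen without RA. Cyct (3.32 ± 0.20, adjusted p = 0.00139), Fmr1nb (2.91 ± 0.19), Mt4 (2.45 ± 0.28) and Ddx3y were again higher in GLP 3A, along with Gstm6 (2.65 ± 0.26), Nxf3 (2.60 ± 0.21), Fam25c (2.58 ± 0.43), Tex19.1 (2.52 ± 0.39) and the metallothionein gene Mt2 (2.39 ± 0.31). Ins2, an insulin gene, was at 7.58 and 2.59 RPKM in RA-treated GLP 3A and listed at 0 in both RA-treated wild-type libraries. Lower in GLP 3A were Crabp1, an RA-binding protein gene, at 10.7 and 28.5 RPKM against 183.5 and 155.3 (-3.19 ± 0.39, adjusted p = 0.0112), the growth factor binding gene Igfbp5 (-2.54 ± 0.35), Il3ra (-2.57 ± 0.20), the heart and limb factor gene Hand2 (-2.48 ± 0.11), Col14a1 (-2.13 ± 0.18), Tfap2b (-2.09 ± 0.49), Lbh (-1.99 ± 0.25) and the semaphorin receptor gene Nrp2 (-1.92 ± 0.22). Atp6v0c-ps2 was lower by -7.02 ± 0.20, and Raet1c,Raet1e was listed at 0 in all 4 GLP 3A libraries against 3.26 and 3.05 RPKM in RA-treated wild type. Igfbp5, Tfap2b and Nrp2 lie on chromosome 1 and Tex19.1 on chromosome 11. Among the 10 largest increases and decreases with RA, short RNA genes listed at 0 in both RA-treated libraries of a genotype were Snord91a, Mir5136 and Mir1186 in wild type and Mir692-1, Snora75, Mir219-2, Snora62 and Mir92b in GLP 3A.

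Further lists differed by less. The RA pathway list was not called (2 higher, 2 lower of 23, 4 and 4 adjusted over the list alone): Stra8 (1.72 ± 0.24) and Hoxb1 were higher, Crabp1 and the retinol dehydrogenase gene Rdh10 (-1.35 ± 0.10, on chromosome 1) lower, and Cyp26a1 (-0.12 ± 0.30) and Rarb (-0.23 ± 0.13) were not called. Sox17 was lower (-1.27 ± 0.27, chromosome 1) and Gata6 at -0.09 ± 0.27. Formative genes were lower in 2 of 15 (3 adjusted over the list alone), among them Zic2 (-1.11 ± 0.27), with Fgf5 at -1.13 ± 0.34 not called. The formative median was -0.40 (adjusted p = 0.00296, and adjusted p = 0.557 with an estimated correlation). Wnt targets were lower in 4 of 12 (4 adjusted over the list alone), with Nkd1 (-1.03 ± 0.22), Sp5 (-1.01 ± 0.17) and Notum (-0.72 ± 0.14). The Wnt target median was -0.40 (adjusted p = 0.0161, and adjusted p = 0.557 with an estimated correlation). Germline genes were higher in 2 of 19 (2 adjusted over the list alone), Tex19.1 and Hormad2 (0.82 ± 0.16), which both lie on chromosome 11. The germline median was 0.28 (adjusted p = 0.00646, and adjusted p = 0.6 with an estimated correlation). The H3K9 methylation machinery was lower in 2 of 26 (1 adjusted over the list alone), Ehmt1 and the demethylase gene Kdm3a (-0.35 ± 0.08). The machinery median was -0.18 (adjusted p = 0.0101, and adjusted p = 0.564 with an estimated correlation). Ribosomal protein, S phase and G2 and M phase genes had medians of -0.18, -0.19 and -0.19 (adjusted p = 9.6e-04, 0.00646 and 0.00198, and adjusted p = 0.557 each with an estimated correlation), with 3 of 77, 2 of 20 and 3 of 20 called (3, 4 and 4 adjusted over the list alone). The ribosomal protein calls include Rpl39l, which was higher in GLP 3A, against the direction of the list median. The germline call ended without RA-treated wild-type replicate 2 (median 0.14, adjusted p = 0.353) or GLP 3A replicate 1 (median 0.12, adjusted p = 0.264), the machinery call without RA-treated wild-type replicate 1 (adjusted p = 0.0518) or GLP 3A replicate 1 (adjusted p = 0.0795), and the Wnt call without RA-treated GLP 3A replicate 2 (adjusted p = 0.0749). Without RA-treated wild-type replicate 1 the germline median was 0.48, and without RA-treated GLP 3A replicate 1 the Wnt median was -0.23.

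In total 1401 genes differed with RA, 700 higher and 701 lower in GLP 3A, 268 of them by 2-fold or more; 617 genes were 2-fold apart in replicate 1 alone and 487 in replicate 2 alone. The standard errors of this comparison rest in part on the untreated libraries, which are not in it, and replicates were not equally close. Across genes, the SD of the log2 difference between replicates was 0.475 in untreated wild type and 0.559 in untreated GLP 3A. With RA it was 0.515 in wild type and 0.695 in GLP 3A. The count of 1401 was 15 with only the 4 RA-treated libraries in the fit, and it depended on each of the 8 libraries. Without untreated wild-type replicate 1 or 2 it was 298 or 301, without untreated GLP 3A replicate 1 or 2 it was 299 or 316, without RA-treated wild-type replicate 1 or 2 it was 339 or 340, and without RA-treated GLP 3A replicate 1 or 2 it was 735 or 2431. In the same order, 26, 26, 26, 26, 26, 25, 36 and 45 of the 46 named genes with a call kept it. In all 8 of these fits 19 kept it, among them Cyct, Fmr1nb, Gstm6, Nxf3, Mt2, Mt4, Ehmt1, Hand2, Col14a1, Il3ra, Nrp2, Rdh10, Hoxa9 and Hoxb1. Calls ended for Nanog without RA-treated wild-type replicate 2 (adjusted p = 0.0613), for Crabp1 (0.0553) and Dppa3 (0.0509) without RA-treated wild-type replicate 1, and for Klf2 (0.0539 to 0.0561) and Tdgf1 (0.0666 to 0.0688) with any 1 of the 4 untreated libraries left out. Klf2 also lost its call without RA-treated wild-type replicate 2 (0.0688), and Tdgf1 without RA-treated wild-type replicate 1 (0.096) or 2 (0.089). The other calls that ended were those of Fam25c, Gata3, Hormad2, Hoxc8, Hoxc9, Hoxc10, Igfbp5, Ins2, Kdm3a, Krt7, Krt19, Lbh, Nkd1, Notum, Rhox9, Sox17, Sp5, Stra8, Tex19.1, Tfap2b, Uty and Zic2.

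Whether the RA response itself differed between the genotypes was tested last. Zfp42, lower in untreated GLP 3A, fell less with RA there, so its responses differed by 2.50 ± 0.41 (SE, n = 2 per group, adjusted p = 0.0463). Ube2l6 (2.59 ± 0.27) and Stmn3 (2.37 ± 0.22) differed in the same way. Pqlc1 (2.48 ± 0.22), Atp2a3 (1.92 ± 0.26), Slc13a4 (1.89 ± 0.24), the natriuretic peptide gene Nppa (1.85 ± 0.31), the casein gene Csn3 (1.72 ± 0.16) and the imprinted gene Phlda2 (1.68 ± 0.25) responded more positively in GLP 3A. More negative responses were those of Atp6v0c-ps2 (-4.96 ± 0.28), Zic2 (-2.83 ± 0.38), Egfl6 (-2.77 ± 0.34), Ubd (-2.57 ± 0.15), the Notch co-activator gene Maml2 (-2.55 ± 0.13), Hand2 (-2.52 ± 0.15), Nrp2 (-2.26 ± 0.31), Col14a1 (-2.24 ± 0.26), the cytokine gene Osm (-2.24 ± 0.14) and the homeobox gene Msx1 (-2.07 ± 0.21). With RA, Ubd reached at most 0.14 RPKM and Osm at most 0.08 in either genotype. Their differences of response therefore reflect the higher untreated levels in GLP 3A. Egfl6 too differed mainly without RA, at 0.85 and 0.79 RPKM in wild type against 9.84 and 8.50 in GLP 3A. Hand2 stood at 0.04 RPKM or less in all untreated libraries and differed with RA. Nanog (1.88 ± 0.43, adjusted p = 0.0854), Klf2 (1.73 ± 0.39, adjusted p = 0.0834), Pou5f1 (1.64 ± 1.05) and Crabp1 (-2.94 ± 0.55, adjusted p = 0.0576) were not called, nor were Ehmt2 (-0.22 ± 0.18), Sox2 (-0.48 ± 0.32), Cyp26a1 (-0.47 ± 0.42), Rarb (-0.27 ± 0.18), Gata6 (-0.25 ± 0.38) and Sox17 (-1.34 ± 0.38).

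Of the lists, 11 had a called difference of responses. The pluripotency list responded more positively in GLP 3A (median 0.44, 0.62 in replicate 1 alone and 0.44 in replicate 2 alone, adjusted p = 2.4e-05, and adjusted p = 0.641 with an estimated correlation), with 1 of 32 genes called (3 adjusted over the list alone). The p53 targets did too (median 0.32, 0.33 in replicate 1 alone and 0.25 in replicate 2 alone, adjusted p = 2.4e-05, and adjusted p = 0.365 with an estimated correlation), with 2 of 20 called (2 adjusted over the list alone), Cdkn1a (0.69 ± 0.09) and Aen (0.60 ± 0.10). Wnt targets responded more negatively (median -0.64, -0.71 in replicate 1 alone and -0.77 in replicate 2 alone, adjusted p = 3.8e-04, and adjusted p = 0.438 with an estimated correlation), with Notum (-1.69 ± 0.19) and Sp5 (-1.49 ± 0.25) the 2 called among 12 (1 higher and 9 lower adjusted over the list alone). Formative genes did as well (median -0.98, -0.85 in replicate 1 alone and -0.61 in replicate 2 alone, adjusted p = 0.00395, and adjusted p = 0.438 with an estimated correlation), with 1 higher and 4 lower of 15 (2 and 9 adjusted over the list alone), Tcf15 (1.05 ± 0.17) against Zic2, Zic5 (-1.46 ± 0.23) and Dnmt3b (-1.38 ± 0.21). Histone genes had a median of 0.23 (adjusted p = 0.00395, and adjusted p = 0.438 with an estimated correlation) with 1 of 30 called (1 adjusted over the list alone). Hox genes had a median of -0.49 (adjusted p = 0.0343, and adjusted p = 0.684 with an estimated correlation) with 1 higher and 3 lower of 32 (1 and 6 adjusted over the list alone), Hoxb1 (0.87 ± 0.12) against Hoxa9 (-1.37 ± 0.16), Hoxd9 (-1.25 ± 0.18) and Hoxa10 (-1.20 ± 0.15). The RA pathway list was not called (median -0.01, mean 0.02, adjusted p = 0.344), with 1 higher and 1 lower of 23 (5 and 4 adjusted over the list alone); Rdh10 (-1.31 ± 0.15) was the lower one. Mesoderm genes had a median of -0.39 (adjusted p = 0.0371, and adjusted p = 0.438 with an estimated correlation) with 2 of 10 lower (4 adjusted over the list alone), Hand2 and Lhx1 (-0.86 ± 0.14). Medians of 0.35 for germline genes, -0.15 for the H3K9 methylation machinery, -0.19 for G2 and M phase and -0.19 for S phase genes were called at adjusted p = 0.0039, 0.0386, 0.0292 and 0.0465 (adjusted p = 0.658, 0.658, 0.641 and 0.438 with an estimated correlation), with 0, 0, 1 and 0 genes called by limma (2, 0, 1 and 0 adjusted over the list alone, and 4, 3, 3 and 1 at an unadjusted p under 0.05). Several of these medians moved with 1 library left out. Without RA-treated wild-type replicate 1 the pluripotency median was 0.75, germline 0.58 and machinery -0.09. Without RA-treated wild-type replicate 2 the Hox median was -0.22, germline 0.22 and histone 0.42. Without RA-treated GLP 3A replicate 1 the pluripotency median was 0.21, formative -0.63, Hox -0.17 and germline 0.14. Without RA-treated GLP 3A replicate 2 the pluripotency median was 0.78, Hox -0.84, germline 0.75 and histone 0.35. The histone median was 0.41 without untreated wild-type replicate 1, 0.48 without untreated GLP 3A replicate 1 and 0.07 without untreated GLP 3A replicate 2. Without the genes of chromosomes 1 and 11, the mesoderm call ended (median -0.13, adjusted p = 0.24). The calls of the machinery (median -0.15, adjusted p = 0.073), G2 and M phase (median -0.17, adjusted p = 0.098) and S phase (median -0.20, adjusted p = 0.073) lists ended as well. Their medians stayed near those with all genes.

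The calls of 6 of these lists ended when 1 library was left out. The Hox call ended without untreated wild-type replicate 1 (adjusted p = 0.0533), untreated GLP 3A replicate 2 (0.0587), RA-treated wild-type replicate 2 (0.178) or RA-treated GLP 3A replicate 1 (0.492). The mesoderm call ended without untreated wild-type replicate 1 (adjusted p = 0.0533), untreated GLP 3A replicate 2 (0.0553), RA-treated wild-type replicate 1 (0.202) or RA-treated GLP 3A replicate 2 (0.239). The germline call ended without RA-treated wild-type replicate 2 (adjusted p = 0.0757) or RA-treated GLP 3A replicate 1 (0.229). The machinery call ended without untreated wild-type replicate 2 (adjusted p = 0.154), untreated GLP 3A replicate 1 (0.0791), RA-treated wild-type replicate 1 (0.193) or RA-treated GLP 3A replicate 1 (0.191). The G2 and M phase call ended without untreated wild-type replicate 2 (adjusted p = 0.0765), untreated GLP 3A replicate 2 (0.0605), RA-treated wild-type replicate 1 (0.193) or RA-treated GLP 3A replicate 2 (0.0653). The S phase call ended without untreated wild-type replicate 2 (adjusted p = 0.122), untreated GLP 3A replicate 1 (0.0922) or 2 (0.0587), RA-treated wild-type replicate 1 (0.202) or RA-treated GLP 3A replicate 2 (0.133). In total 238 genes differed in response, 74 more positive and 164 more negative in GLP 3A, 149 of them by 2-fold or more; 721 genes were 2-fold apart in replicate 1 alone and 567 in replicate 2 alone. The count was 12 or 11 without untreated wild-type replicate 1 or 2, 17 or 19 without untreated GLP 3A replicate 1 or 2, 47 or 69 without RA-treated wild-type replicate 1 or 2, and 1128 without RA-treated GLP 3A replicate 2. Of 33 named genes with a call, 5, 4, 6, 5, 12, 11, 29 and 33 kept it with these libraries left out in the same order, RA-treated GLP 3A replicate 1 included. Ubd, Hand2, Maml2 and Atp6v0c-ps2 kept it in all 8 of these fits, and the 29 others did not. The Zfp42 call ended without untreated wild-type replicate 1 (adjusted p = 0.2) or 2 (0.2), untreated GLP 3A replicate 1 (0.201) or 2 (0.18), or RA-treated wild-type replicate 1 (0.0802) or 2 (0.119).

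Across genes the RA responses of the genotypes were alike in both rising and falling genes. Of the genes that rose in wild type, 3733 also rose in GLP 3A (83.8%; 1438 for independent lists), and of those that fell 4100 also fell (89.4%; 1747.5 for independent lists). Pearson's r between the responses was 0.879 over 13198 genes. With 1 replicate on each side it was 0.874 within wild type, 0.831 within GLP 3A and 0.785 to 0.836 between genotypes. The genotype differences without and with RA shared 252 higher genes (52.7 for independent lists), led by Cyct, Fmr1nb, Gstp2 and Mt4, and 183 lower genes (29.1), Atp6v0c-ps2 and Il3ra among them. Of the shared genes, 77 of the higher lie on chromosome 11 and 85 of the lower on chromosome 1. Their r was 0.309 over all genes; with 1 replicate on each side it was 0.431 within the untreated state, 0.347 with RA and 0.188 to 0.253 across states. Genes are not independent replicates, so no p-value is given for r.

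Replicate 2 differed from replicate 1 in liver genes in every group. Alb, the gene of serum albumin, which was chosen after its values were seen, stood at 3.14 RPKM in replicate 1 and 257.6 in replicate 2 of untreated wild type, 5.64 and 446.3 in untreated GLP 3A, 1.07 and 177.1 in RA-treated wild type, and 2.65 and 519.9 in RA-treated GLP 3A. In all 4 groups 134 genes were at least 4-fold higher in replicate 2, and 29 of 30 liver genes on a list made after the data were seen were among those 4-fold higher. The list shares 2 genes with the endoderm list reported above. As replicate numbers are balanced over the groups, each comparison holds a replicate 1 and a replicate 2 library on both sides. The amount was not balanced between the genotypes. In replicate 2 these 29 liver genes summed to 639.2 RPKM in wild type and 1155.6 in GLP 3A without RA. With RA the sums were 466.6 and 1395.0. Differences of liver genes between the genotypes can therefore not be credited to the mutation.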

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

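Of the tests below, the tests of a single share of untreated cells and of a weaker RA response as a whole were chosen only after the result was seen.

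The RA response of GLP 3A cells differed from that of wild-type cells in 238 genes and 11 lists. List medians of the difference were 0.44 for pluripotency, -0.98 for formative and primed pluripotency, -0.49 for Hox, -0.39 for mesoderm, 0.35 for germline, -0.15 for the H3K9 methylation machinery, 0.32 for p53 targets, -0.64 for Wnt targets, -0.19 for G2 and M phase, -0.19 for S phase and 0.23 for histone genes. With an estimated correlation 0 of the 11 were called (adjusted p = 0.365 to 0.684), and the calls of 6 ended when 1 library was left out. Single genes with a more positive response in GLP 3A were Ube2l6 (2.59), Zfp42 (2.50), Pqlc1 (2.48), Stmn3 (2.37), Atp2a3 (1.92), Slc13a4 (1.89), Nppa (1.85), Csn3 (1.72), Phlda2 (1.68), Tsix (1.14), Tcf15 (1.05), Hoxb1 (0.87), Cdkn1a (0.69) and Aen (0.60). Those with a more negative response were Atp6v0c-ps2 (-4.96), Zic2 (-2.83), Egfl6 (-2.77), Ubd (-2.57), Maml2 (-2.55), Hand2 (-2.52), Nrp2 (-2.26), Col14a1 (-2.24), Osm (-2.24), Msx1 (-2.07), Notum (-1.69), Sp5 (-1.49), Zic5 (-1.46), Dnmt3b (-1.38), Hoxa9 (-1.37), Rdh10 (-1.31), Hoxd9 (-1.25), Hoxa10 (-1.20) and Lhx1 (-0.86). Ubd and Osm were near 0 RPKM with RA in both genotypes, so theirs reflect the untreated levels. Other genes, such as Tcf15 and Dnmt3b, also differed mainly without RA. Untreated Tcf15 stood at 47.2 and 53.9 RPKM in wild type and 21.8 and 19.6 in GLP 3A. With RA it stood at 2.40 and 2.60 against 2.33 and 1.79. Others, such as Hand2, differed only with RA. A difference of responses alone does not tell in which state the genotypes differ.

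With RA, 7 of 32 pluripotency genes were higher in GLP 3A cells than in wild type, Nanog among them. The liver RNA and lower depth of replicate 2 are argued against by replicate 1 alone, where the list median was 0.66, and a single share of cells left in the untreated state as the whole of the Nanog difference by the 38.5% and 45.3% of genes whose excess was below 1 part in 3 of the Nanog share (6.0% and 2.73% of the untreated level, against 4.51% and 2.5% for Klf2, 1.48% and 0.886% for Pou5f1 and 0.21% and 0.0179% for Trh). A remainder of undifferentiated cells of a mixed kind might account for part of it and stays open: of genes that fell at least 20-fold in wild type, 92.3% of 52 and 85.2% of 54 were higher in GLP 3A. A weaker RA response as a whole stays open too, since the RA pathway list had a median difference of -0.01 over members that went both ways (5 higher and 4 lower adjusted over the list alone), which decides nothing. Among genes with a 4-fold mean response chosen in the other replicate number, the strength of response in GLP 3A minus wild type had medians of -0.26 and -0.18 over 676 and 625 rising genes and -0.19 and -0.04 over 425 and 373 falling genes.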

How the results depend on the processing

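The tests with suspect zeros as missing, without genes 4-fold higher in replicate 2, without short RNA genes, without chromosomes 1 and 11 and with each replicate number alone were chosen only after the results were seen. The 1541 genes called without RA became 1011 with quantile normalization, 991 without chromosomes 1 and 11, 3450 with only the 4 libraries compared, 277 at 2-fold and 206 to 2298 with 1 library left out. The 1401 called with RA became 724 without these chromosomes, 15 with only the 4 libraries, 268 at 2-fold and 298 to 2431 with 1 library left out. At 2-fold, 3388 genes differed between RA-treated and untreated cells in wild type and 3570 in GLP 3A. The 238 genes with different responses became 158 with a pseudocount of 0.1, 130 with quantile normalization, 362 with robust empirical Bayes, 427 with suspect zeros as missing, 149 at 2-fold and 11 to 1128 with 1 library left out. The r between RA responses was 0.929 without short RNA genes and 0.831 to 0.873 with 1 library left out, and the r between genotype effects was 0.278 without a filter, 0.414 without short RNA genes and 0.222 to 0.333 with 1 library left out. The causes of these shifts were not tested.

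Signs turned only in small differences without a call and in the ribosomal protein list, among the named genes and lists. Ehmt1 was at 0.003 with median-of-ratios scaling in the RA response of GLP 3A, and the ribosomal protein list at 0.06 in wild type and 0.14 in GLP 3A (adjusted p = 0.0327, a call in the other direction) with quantile scaling. With 1 library left out, the genotype differences without RA ranged from -0.162 to 0.007 for Ehmt2, -0.024 to 0.093 for Rarb and 0.000 to 0.143 for Sox17. With RA they ranged from -0.139 to 0.742 for Zfp42, -0.514 to 0.279 for Cyp26a1 and -0.423 to 0.233 for Gata6. The RA response of Crabp1 in GLP 3A ranged from -1.168 to 0.162, and the difference of responses from -0.579 to 0.076 for Gata6. Of 5003 values for named genes under other settings, 4466 kept their sign and stayed called or uncalled, 499 lost their call, 26 gained one and 12 turned sign. Of 1040 such values for lists, the estimated correlation apart, 967 kept their call and sign, 71 lost the call and 2 turned. With repeated symbols treated otherwise nothing could change, since no symbol is repeated.

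By the labels the samples of different groups share only a replicate number, and none says that a number marks a shared culture or day. The replicate 2 libraries do have liver transcripts and a lower depth in common, and what else a number marks is open. Deviations from the group means of same-numbered samples had r of 0.277, 0.169, 0.226, 0.313, 0.355 and 0.328 over the 6 pairs of groups. With a replicate block the counts were 1741 without RA, 1647 with RA, 9308 and 9601 for RA in wild type and GLP 3A, and 199 for the difference of responses. The block ended the mesoderm call in wild type (adjusted p = 0.0535) and in the difference of responses (adjusted p = 0.0635), and the calls of Pisd-ps3 without RA and of Nppa, Tcf15, Aen, Hoxd9 and Lhx1 in the difference of responses. It added calls of Ehmt2 and Lin28a in wild type and changed no other call of a named gene and ended no other list call.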

Other observations

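The test of autosomes other than chromosomes 1 and 11, and the tests of liver RNA, of newborn or fetal liver and of hepatic differentiation, were chosen only after the results were seen.

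Genes called in both states were picked here after their values were seen, so they say nothing of the families they belong to. Without RA and with RA, the metallothionein gene Mt1 differed by 1.29 ± 0.26 (adjusted p = 0.0285) and 1.91 ± 0.26 (adjusted p = 0.0143), Mt2 by 1.42 ± 0.31 and 2.38 ± 0.31, the glutathione transferase genes Gstm3 by 2.06 ± 0.11 and 0.95 ± 0.11, Gstm6 by 1.06 ± 0.26 and 2.65 ± 0.26 and Gstp2 by 3.07 ± 0.34 and 2.24 ± 0.34. On the X chromosome, Pnma5 (3.02 ± 0.14 and 2.07 ± 0.14), Klhl13 (2.75 ± 0.21 and 1.69 ± 0.21) and Nxf3 (2.06 ± 0.20 and 2.60 ± 0.20) were higher in both states. Of the imprinted genes, H19 was higher (1.41 ± 0.16 and 0.91 ± 0.16) and Grb10 lower (-1.27 ± 0.18 and -1.31 ± 0.18) in both. Whether any of these genes is a direct target of GLP was not tested.

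Genes on chromosomes 1 and 11 made up 416 of the 1541 calls without RA (27.0%) and 438 of 1401 with RA (31.3%), against 13.8% of the genes tested. Of 273 genes within 20 Mb of Ehmt1, 28 were called (10.3% against 11.7% of all genes tested, one-sided Fisher's exact p = 0.796). The 11.7% includes the many calls on chromosomes 1 and 11, so this test cannot decide whether linked variants near Ehmt1 play a part. Chromosome 1 lay -0.28 from the median of all genes, past the limit of 0.25 set before, and all 10 of its 20-Mb bins were negative and all 7 of chromosome 11 positive without RA, so a different copy number in part of the cells may account for chromosome 1. Chromosome 11 lay 0.19 from that median without RA, short of the limit, and 0.25 with RA; over its 636 genes at 5 RPKM or more it lay 0.24 and 0.29 from the other autosomes, with 7 of 7 bins positive in both states, and for it the same explanation stays open. Over the 367 genes of chromosome 1 at 5 RPKM or more, the median lay -0.35 from that of the other autosomes, which a loss of 1 copy in 43% of GLP 3A cells or a gain in 54% of wild-type cells would give; which line differs stays open. For the 1125 genes called elsewhere, a different copy number of the whole autosomes they lie on is argued against. The other autosome farthest from the median of all genes, chromosome 18, lay -0.04 from it. Such medians cannot show whether a copy number of chromosomes 1 and 11 changed genes elsewhere, which was not tested. Differences between clones other than the mutation stay open there too.

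The 4 Y-linked genes tested were higher in GLP 3A cells in both states, by unequal amounts: without RA Kdm5d stood at 0.068 RPKM in wild type and 3.15 in GLP 3A, and Uty at 3.35 and 6.23. A second X chromosome in the wild-type cells is argued against by the X-linked median, which lay 0.012 from the autosomal median. Loss of the Y chromosome from wild-type cells may account for the difference, with reads of X-linked copies left in Uty and Eif2s3y, and was not tested.

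Liver genes in the replicate 2 libraries may come from liver RNA or cDNA mixed in: between pairs of these libraries the ratios of 29 liver genes scattered by at most 0.232 (median absolute deviation, log2). Of genes on lists of other tissues, 0 of 11 of fetal liver and blood, 0 of 9 of intestine, 0 of 10 each of kidney, skeletal muscle, pancreas, brain and immune genes were 4-fold higher in replicate 2 in all 4 groups, against 29 of 30 for liver. These counts do not exclude blood or immune transcripts. Beta-s, a beta-globin gene on none of these lists, was 4-fold higher in all groups. The immune gene Lyz2 went from 0.47 to 5.95 RPKM in untreated wild type and from 1.66 to 4.62 in untreated GLP 3A. With RA it went from 0.10 to 2.79 and from 0.40 to 19.5. At 5 RPKM or more in at least 1 replicate 1 library were 2 liver genes, Apoa2 and Alb. Alb was so only in untreated GLP 3A, at 5.64 RPKM, and whether the stem cells made it was not tested. From the other lists 2, 0, 1, 3, 1, 2 and 2 genes reached this level, in the order above. On a list fixed before are also 2 liver and 2 fetal liver and blood genes. Newborn or fetal liver is argued against by Afp at no more than 0.0207% of Alb, and hepatic differentiation of the cells by Alb, which without RA stood at 145% of its RA level in wild type and 85.9% in GLP 3A. Where such RNA entered stays open, and its share differs between libraries, with more in GLP 3A than in wild type in both states.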
